A study of Mus musculus with 106 samples.

How the data were processed

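RNA from liver, adipose tissue and skeletal muscle of male C57BL/6 mice was hybridised to 106 single-colour Agilent arrays that carried probes for mRNAs and long noncoding RNAs. Per the labels, total RNA was extracted with Trizol, ribosomal RNA was removed, and Cy3-labelled cRNA was made from random primers along whole transcripts. Per the labels, the mice were fed, fasted for 24 h, or fasted for 24 h and refed for 4 h. Other mice received chow, a high-fat diet with 60% of kcal from fat for 48 h, or that diet for 12 weeks. A further set compared ob/ob mice, which lack leptin, with lean controls at 10 weeks of age. The labels give an age of 20 weeks for the fed, fasted and refed mice and 18 weeks for the 48 h diet mice. They give a food withdrawal of 4 to 5 h for the chow, high-fat diet, wild-type and ob/ob mice.

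Each array came as a scanner file. Per the file headers, the spot intensities were extracted with Agilent Feature Extraction 10.7.3.1, a version that the submitters' processing notes also give, and the array design names the mouse build mm9. The processed intensity of a spot is, per the file headers, the Cy3 brightness after background subtraction by the scanner software, with no scaling between arrays. The other columns used, per the file headers, are flags of 0 or 1 that mark outlier spots, saturated spots and spots well above background. The authors also deposited 1 table of log2 intensities for 30063 probes of the same arrays. Its columns correlated with the log2 scanner values of the same array at r = 0.987 or more, and their medians lay between 8.33 and 8.42, so the scale is log2 without centring per probe. The tool and the filter behind the deposited log2 table are not given in the sources used here.

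The main values were log2 of the processed intensity minus the 75th percentile of the array. Control spots, spots of probes named as negative, and spots marked as outliers were left out, saturated spots were kept, and spots of 1 probe were averaged. A symbol with several probes was represented by the probe with the highest mean over the 106 arrays. This gave 59705 features. The files give no gene name for 51842 of them, which carry only codes of the array maker. Another 5365 carry long intergenic noncoding RNA (lincRNA) names without a gene, and 112 could be given a gene symbol through RefSeq accessions in the reference table. The rest are 1424 transcript or expressed sequence tag accessions without a symbol and 962 genomic regions. Gene names and lincRNA names are therefore those of a small part of the array, and codes without a name are counted but not listed.

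Groups were compared with limma 3.58.1 in R 4.3.3, with data.table (version 1.17.8) for reading, in 9 separate fits, 1 for each tissue and experiment. A feature entered a fit if it was well above background on every array of at least 1 group of the fit and measured on at least 2 arrays of each group. A feature was called changed at a Benjamini-Hochberg adjusted p under 0.05. Differences between tissues were tested with the F-test of the tissue by state interaction in 1 model of the 3 tissues, without a slide term. Within an experiment the labels give arrays of different tissues the same code numbers and do not say whether a number marks 1 animal. As a random block the number had correlations of -0.0307 to 0.0631. Folds are 2 to the power of the log2 difference, errors are limma's standard errors (SE), and n is the number of arrays per group. A probe that was not well above background on any array of a group has only a bound there. In that case the fold is given as "at least", from the bright group's mean and, on each array of the dim group, the higher of the probe's own signal and the lowest signal among probes well above background. This bound holds for the main values only, and normexp gave a smaller fold for each such probe named. The sample labels give 4 or 5 biological replicates per condition. The p-values measure the spread between these samples, which includes the animal, the RNA extraction and the array.

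Arrays with the same recorded scan date were taken to share a slide, which put the 106 arrays on 15 slides. The slides named below are therefore inferred from the scan. The slide was treated as a batch. Where a slide held arrays of more than 1 group, it was added as a fixed block, and the comparison was also made within 1 slide that held at least 2 arrays of each group. Where each slide held 1 group but a group spanned several, it was added as a random block. In liver refed against fasted, muscle 12-week diet against chow, muscle ob/ob against wild type and muscle 12-week against 48 h diet each group lay on a slide of its own, and no slide term could be fitted. No slide held both groups in liver and adipose 12-week diet against chow and in adipose 12-week against 48 h diet either. There the fixed block in liver was linked only through the 48 h arrays, and the random block in adipose tissue cannot separate the diet from the slide.

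The comparisons, the alternatives and the rule for named genes were set before the data were examined, except that the comparison within 1 slide and the percentile over features detected on every array of the fit were chosen after seeing the data. The alternatives were normexp background correction with an offset of 50, quantile normalization, no filter or a stricter filter on dim probes, the deposited log2 table, the slide block, the replicate number as a block, all arrays of a tissue in 1 fit, a trended and robust variance, other ways to treat the probes of a gene, an adjusted p under 0.01 or a fold of at least 1.5, and leaving out each array. The offset of normexp shrinks the log2 differences of dim probes. The mean signal planned for normexp was not used here, so the median signal and the median background stood in for it. By the rule, the named genes were, among changed features with a symbol whose 2 groups did not overlap, the 5 with the largest rise and the 5 with the largest fall per comparison (3 and 3 for the 12-week against the 48 h diet), the 2 lincRNA probes with the largest rise and the 2 with the largest fall, and the 5 genes with the largest F in each test between tissues. The text leaves some of them out of the comparisons, so those shown may look steadier than the whole set. In ob/ob adipose tissue Ssty1, Gm20831, Gm14819 and Gm10488, which rose more than Gusb, lost their calls with the slide block. Calls were lost in 15 of 19 alternatives for humanlincRNA2254-_P1 in refed muscle, and in 12 of 19 for Taf1a in ob/ob muscle. Others left out lost none, such as Fam177a2 in ob/ob liver over 23 alternatives. Outside the rule, after their values were seen, these were also named: Tfrc in fasted liver, Hmgcs1 and Hhipl2 in refed liver, Gk in ob/ob liver, Taf1a in adipose tissue after 48 h, and Mia3, Ccl21b, Ccl21c and Gm13304 in adipose tissue after 12 weeks.

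The 37 gene lists and 59 marker genes chosen beforehand could not be used. Of the 590 genes on the lists only 3 (Hmgcs1, Gapdh and Gk) had a named probe, none of the lists (0) had 5 named members, and 0 of the 59 marker genes had a named probe. Tests of gene lists with camera and fry were therefore not run, and pathways and cell types are not reported. Probes for near-identical genes, such as Ccl21b, Ccl21c and Gm13304 or the vomeronasal receptors of the Vmn1r family, may share target RNA and were not separated. Vmn1r and other genes of large families are therefore uncertain as to the member.

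The method was tested on simulated data made from the real arrays. Noise was drawn independently for each feature from its own spread, without slide differences, and 200 features were changed in each simulation. The shares and false calls below therefore do not describe fits with many changed features or with slide differences. With 4 arrays per group in liver fasted against fed, 38% of features changed 2-fold and 84% of those changed 4-fold were recovered. In adipose ob/ob against wild type with 5 arrays per group, these shares were 48% and 82%. In muscle 12-week diet against chow, they were 32% and 76%, and between 5 and 11 false calls were made in the 3 simulations. The number of arrays limits the precision. No replicate pair held identical values, and the lowest correlation between replicates was 0.845, in fasted adipose tissue. The labels of 18 arrays name a tissue that conflicts with another field of the same label. All 106 arrays, these 18 included, correlated best with the arrays of the tissue in their title. The margin was small in liver of the feeding experiment, with 0.0156 as the lowest. Fasted liver 1 had r = 0.798 with liver and 0.782 with adipose tissue.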

Results

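Expression of mRNAs and long noncoding RNAs was measured in liver, adipose tissue and skeletal muscle of male mice in 5 metabolic conditions and their controls. The feeding experiment compared mice fed freely, mice fasted for 24 h and mice refed for 4 h after the fast. The diet experiment compared chow with a high-fat diet given for 48 h or for 12 weeks. The genetic experiment compared ob/ob mice, which are obese because they lack leptin, with lean wild-type mice. Each of the 24 groups held 4 arrays in the feeding experiment and in all muscle groups, and 5 arrays in the diet and ob/ob groups of liver and adipose tissue. Fed and fasted mice were killed at 10 am and refed mice at 2 pm, so refeeding and the time of day changed together. In the diet and ob/ob experiments food was withdrawn for 4 to 5 h, also from the controls.

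Between 36.9% and 94.8% of the features on an array were well above background. By the same flag, 3.25% to 87.8% of the spots of probes named as negative were above background, so the flag does not prove detection. The 12 liver arrays of the feeding experiment had 36.9% to 52.6% of features above background, against 45.5% to 94.8% on the others, and held up to 115 saturated features, against at most 1 on any other array. The log2 75th percentile was 7.34 ± 0.96 (SD, n = 4) in fed liver, 6.37 ± 0.45 (n = 4) in fasted liver and 8.12 ± 0.24 (n = 4) in refed liver. Fasted adipose replicate 4 stood apart, with 45.5% of its features above background against 76.7% to 79.5% on the other fasted adipose arrays. A gene symbol could be given to 112 features and a lincRNA name to 5365, so named genes describe a small part of each comparison. The files do not pair the lincRNA probes with gene names, and they are given by probe name, in which + and - mark the strand. For each gene named below as called in a comparison of 2 groups, without a remark, all arrays of 1 group lay above all arrays of the other.

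**Figure D1:**
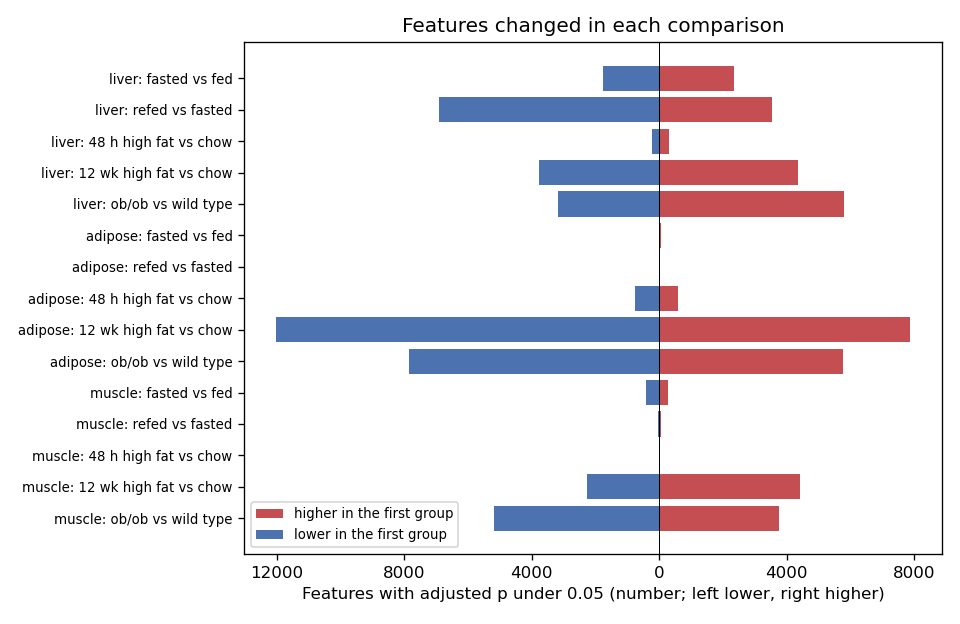
Number of features with an adjusted p under 0.05 in each of 15 comparisons, drawn to the right if higher and to the left if lower in the first group. The largest count was 19910 in adipose tissue after 12 weeks of high-fat diet.

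In fasted liver, Gk, the glycerol kinase that feeds glycerol into gluconeogenesis, rose 3.49-fold over fed liver (log2 1.80, SE 0.18, n = 4 per group). Hhipl2 rose 5.32-fold (log2 2.41, SE 0.21) and Hprt, an enzyme of purine salvage, 3.79-fold (log2 1.92, SE 0.30, with 3 fed arrays). Tuba1b, an alpha-tubulin, fell 4.96-fold (log2 -2.31, SE 0.28), and Hmgcs1, which makes HMG-CoA for cholesterol synthesis, fell 3.90-fold (log2 -1.96, SE 0.46, with 3 fed arrays). Tfrc, the transferrin receptor that takes up iron, rose by a log2 value of 1.18 (SE 0.30), a gene chosen after its values were seen and with overlapping groups. The lincRNA probe MM9LINCRNAEXON10296+_P1 rose 54.98-fold and MM9LINCRNAEXON11432-_P1 rose 14.2-fold, while MM9LINCRNAEXON11065-_P1 fell 5.35-fold. The first 2 had log2 values of 5.78 and 3.83, against 5.04 and 3.11 with normexp and 4.57 and 3.03 in the deposited log2 table. Hhipl2 had 1.59 with normexp, and Hmgcs1 and Tuba1b had -2.72 and -2.95 after quantile normalization. MM9LINCRNAEXON10531-_P1 was at least 2.18-fold lower, since no fasted array had it above background, but its log2 value was -2.05 as fitted and -0.23 with normexp. Of 52 named genes tested, 7 were higher and 4 lower in fasted liver. Over all 24448 features, limma called 4111 (2342 higher and 1769 lower). All 8 arrays lay on 1 slide, and a fit of these arrays alone called 3444. Without fasted replicate 2, 2673 features were called. The share of higher calls was 57.0%, against 46.6% after quantile normalization and 43.4% with normexp. The call of Hprt was lost after quantile normalization (log2 0.68, adjusted p 1.21e-06 to 0.273 over its alternatives). That of Hmgcs1 was lost without fed replicate 4 and without the filter on dim probes (0.000425 to 0.0592). Tfrc lost its call after quantile normalization, with normexp, without the filter and without any 1 of fed 3, fed 4, fasted 2, fasted 3 or fasted 4 (0.00851 to 0.242), and MM9LINCRNAEXON10531-_P1 with normexp, without the filter and without fed 1, fasted 2 or fasted 4 (0.000202 to 0.567).

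After 4 h of refeeding, Gk fell 3.04-fold in liver (log2 -1.60, SE 0.18, n = 4 per group) and Hhipl2 fell 2.16-fold (log2 -1.11, SE 0.21). Csprs fell 2.30-fold (log2 -1.20, SE 0.27). Actb, the cytoplasmic beta-actin, rose 1.89-fold (log2 0.91, SE 0.20), and Disp1, which releases Hedgehog proteins from cells, rose 1.81-fold (log2 0.86, SE 0.19). Hmgcs1 rose 2.21-fold (log2 1.14, SE 0.42) with overlapping groups. Hmgcs1 and Hhipl2 were chosen here after their values were seen. MM9LINCRNAEXON10971-_P1 was at least 9.18-fold higher, MM9LINCRNAEXON11375-_P1 at least 5.00-fold lower, and MM9LINCRNAEXON10560-_P1 fell 9.21-fold. Their log2 values were 4.96, -4.14 and -3.20 as fitted and 1.80, -2.02 and -2.58 with normexp, and the last was -2.12 in the deposited log2 table. Hmgcs1 had 1.84 after quantile normalization. Of 52 named genes, 8 were higher and 22 lower. B2m and Ppia were saturated on all 4 refed arrays, so their lower values there are no measure of a change. In all, limma called 10447 of 24448 features, 3541 higher and 6906 lower. The refed arrays lay on a slide of their own, so refeeding and slide cannot be told apart. The share called higher was 33.9%, 47.6% in the deposited log2 table and 59.6% with the percentile over features detected on every array. With that percentile the median log2 difference of all features moved from -0.24 to 0.07. The call of Hmgcs1 was lost without the filter and without fasted 1, 2 or 4 or refed 1 or 4 (adjusted p 0.00275 to 0.129).

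A high-fat diet of 48 h raised 1 of 82 named genes in liver. Hmgcs1 was 3.15-fold higher than on chow (log2 1.66, SE 0.34, n = 5 per group). The lincRNA probe MM9LINCRNAEXON10517+_P1 rose 3.93-fold and MM9LINCRNAEXON11934-_P1 fell 2.12-fold. The log2 value of the first was 1.97, and 1.05 with normexp. The limma fit called 554 of 42851 features, 326 higher and 228 lower. With the slide as a block 17 were left, and within the slide that held all 5 chow and 3 of the diet arrays there were 0 (4389 at an unadjusted p under 0.05). Leaving out any 1 of the 10 arrays moved the count by more than 1.5 times, to 67, 253, 76, 1616 and 192 without chow 1 to 5 and to 1754, 225, 131, 171 and 73 without diet 1 to 5. Hmgcs1 had a log2 difference of 1.73 with the block and within the slide, and its call was lost in both, without the filter, and without chow 1, 3 or 5 or diet 2, 3, 4 or 5 (adjusted p 0.00495 to 0.179). MM9LINCRNAEXON10517+_P1 lost its call in the same 3 fits and without any array other than chow 4 or diet 1 (0.00349 to 0.246). MM9LINCRNAEXON11934-_P1 lost it in both slide fits and without chow 1, chow 3 or diet 5 (0.00639 to 0.246).

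After 12 weeks of the diet, Hmgcs1 was 2.74-fold higher in liver than on chow (log2 1.45, SE 0.34, n = 5 per group). Ldhal6b, a lactate dehydrogenase of the A type, rose 4.06-fold (log2 2.02, SE 0.39), and BC147527 rose 2.99-fold (log2 1.58, SE 0.37, above background on 4 of 5 chow arrays). The probe mouselincRNA0491-_P1 fell 6.56-fold (log2 -2.71, SE 0.36), and MM9LINCRNAEXON11950-_P1, above background on 4 of 5 chow arrays, rose 5.17-fold (log2 2.37, SE 0.42). With normexp BC147527 was at 0.83 and MM9LINCRNAEXON11950-_P1 at 1.21. Of 82 named genes, 9 were higher and 1 lower. There were 8139 called features of 42851, 4370 higher and 3769 lower, and normexp moved the higher share from 53.7% to 39.7%. No slide held both groups. With the slide as a block, which links them only through the 48 h arrays, 434 features were called, 92 higher and 342 lower. The median SE of the main calls rose from 0.238 to 0.392, and the block's log2 difference was 0.689 times the first (median ratio). With the block, mouselincRNA0491-_P1 kept its call (log2 -2.91), while those of Hmgcs1 (log2 1.63, adjusted p 0.00237 to 0.261 over its alternatives), Ldhal6b (log2 0.31, 0.00198 to 0.878), BC147527 (log2 0.25, 0.00305 to 0.918) and MM9LINCRNAEXON11950-_P1 (log2 0.69, 0.0010 to 0.695) were lost. Without 12-week replicate 2 there were 5080 calls and without 12-week replicate 5 there were 5197.

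**Figure D2:**
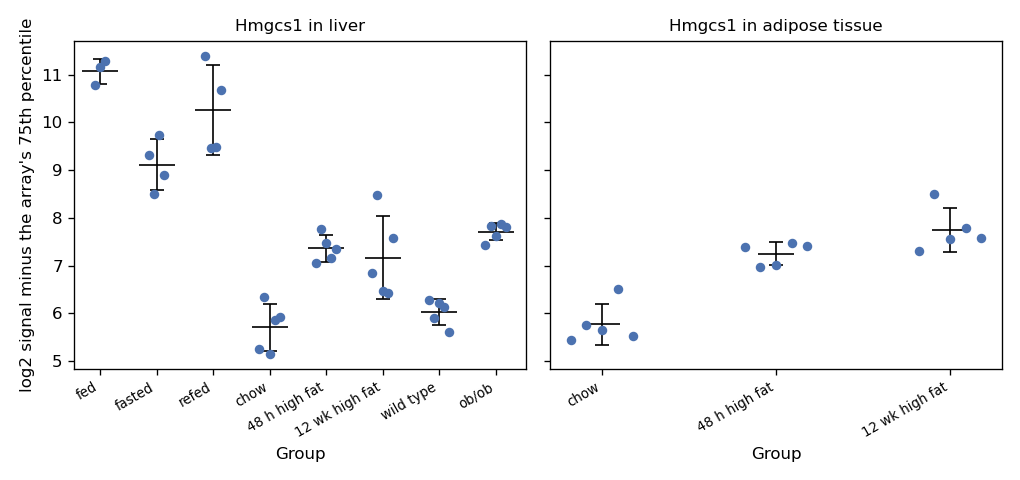
Hmgcs1 on each array, as log2 signal minus the 75th percentile of the array, in liver (left) and in adipose tissue of the diet experiment (right). Points are arrays, bars are the mean and SD of a group, 1 fed liver array was left out as an outlier spot, and levels are comparable within an experiment only. On the log2 scale Hmgcs1 fell by 1.96 in fasted against fed liver and rose by 1.68 in ob/ob against wild-type liver.

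In the liver of ob/ob mice Hmgcs1 was 3.21-fold (log2 1.68, SE 0.16, n = 5 per group), Hhipl2 4.53-fold (log2 2.18, SE 0.25) and Tfrc 2.92-fold (log2 1.55, SE 0.28) above wild type. Gk, chosen after its values were seen, rose 1.57-fold (log2 0.65, SE 0.16). Hprt rose 2.29-fold (log2 1.20, SE 0.14). Mia3, which loads large cargo such as collagen at exit sites of the endoplasmic reticulum, was lower (log2 -0.80, SE 0.23), as was B020031M17Rik (log2 -0.93, SE 0.25). Among lincRNA probes, MM9LINCRNAEXON10679-_P1 rose 7.62-fold and MM9LINCRNAEXON10179-_P1 rose 6.26-fold, while MM9LINCRNAEXON10398-_P1 fell 23.6-fold and MM9LINCRNAEXON11429-_P1 fell 26.6-fold (above background on 4 of 5 ob/ob arrays). Both had smaller log2 differences of -3.96 with the slide block, against -4.56 and -4.74 without it, and the latter had -4.15 without ob/ob 5 and -3.55 with normexp. In the deposited log2 table they had -5.38 and -5.46. MM9LINCRNAEXON10679-_P1 and MM9LINCRNAEXON10179-_P1 had 2.93 and 2.65, against 2.23 and 1.74 with normexp. Of 88 named genes, 19 were higher and 3 lower. The 8974 called features of 47909 were 5794 higher and 3180 lower. A slide block gave 7799 calls, 6538 of them in both fits with the same direction, and 7533 were called within the slide that held all 5 wild-type and 3 of the ob/ob arrays. Between these 3 and the other 2 ob/ob arrays, on another slide, 7827 features were called. The median log2 difference of all features was 0.15, and 0.04 after quantile normalization. The slide block ended the call of Mia3 (log2 -0.44), which was also lost within the slide and without wild type 2, 4 or 5 or ob/ob 4 or 5 (adjusted p 0.00613 to 0.0798). That of B020031M17Rik was lost with the block (log2 -0.69), with all liver arrays in 1 fit and without wild type 2 (0.00208 to 0.143).

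No named gene passed the threshold in fasted against fed adipose tissue: limma called 0 of 88, with 16 at an unadjusted p under 0.05. The lincRNA probes MM9LINCRNAEXON10644-_P1 and MM9LINCRNAEXON10007-_P1 rose 3.85-fold (log2 1.94, SE 0.32, n = 4 per group) and 2.92-fold (log2 1.55, SE 0.25). Of 43684 features 60 were called, 48 higher and 12 lower. With the slide as a block 1 was left, and within the slide that held all 4 fasted and 2 of the fed arrays limma called 0 (1608 at an unadjusted p under 0.05). The count was 6, 6, 7 and 16 without fed 1 to 4, 7, 22 and 752 without fasted 1 to 3. In the slide fits the log2 values were 1.78 and 1.27, and with normexp the first was 1.28. Both lincRNA calls were lost there, with the replicate block, without the filter, with the percentile over features detected on every array and without any 1 of the fed arrays, fasted 1 or fasted 2, and MM9LINCRNAEXON10007-_P1 also without fasted 4 (adjusted p 0.00109 to 0.982 and 9.27e-06 to 0.982). Of the calls 80% were higher, and 57.1% with that percentile, which moved the median log2 difference of all features from -0.01 to -0.22, while normexp moved it to 0.27.

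For refeeding in adipose tissue limma called 0 of 88 named genes, with 11 at an unadjusted p under 0.05. The adipose fit of fasting and refeeding had a median SE of 0.415 over all features. It was 0.210 in the adipose diet fit and 0.2 in ob/ob. The few calls therefore do not show that adipose tissue did not respond, and all adipose arrays in 1 fit gave many more, as given below. No lincRNA probe was called (0 of 3218). The 8 called features of 43684, 3 higher and 5 lower, carry only codes. Their higher share was 37.5%, 27.5% after quantile normalization and 23.4% with normexp, and the median log2 difference of all features was -0.11, -0.01 and -0.24. With the slide as a block limma called 0 (2154 at an unadjusted p under 0.05), and within 1 slide 0 (1052). Between the refed arrays on 2 slides, with 2 arrays on each, 1952 features were called. The count was 0, 1, 570 and 14 without fasted 1 to 4 and 0, 3 and 3 without refed 1, 3 and 4.

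Adipose tissue after 48 h of high-fat diet had 2 called genes among 96 named ones. Hmgcs1 rose 2.78-fold over chow (log2 1.48, SE 0.24, n = 5 per group). Taf1a, part of the factor that starts ribosomal RNA synthesis by RNA polymerase I, fell 1.92-fold (log2 -0.94, SE 0.22) with overlapping groups and was chosen after its values were seen. MM9LINCRNAEXON11365-_P1 (above background on 4 of 5 chow arrays) rose 5.23-fold and MM9LINCRNAEXON10875+_P1 rose 3.58-fold, while MM9LINCRNAEXON10507-_P1 fell 3.09-fold. The first and the last had log2 values of 2.39 and -1.63, and 1.32 and -0.98 with normexp. There were 1338 calls among 44655 features, 588 higher and 750 lower. The slide block left 228 (134 higher and 94 lower), and 248 (160 higher and 88 lower) were called within the slide that held all 5 diet and 3 of the chow arrays. Between these 3 and the other 2 chow arrays 305 features were called. Hmgcs1 kept its call in both (log2 1.36, adjusted p 0.0439 with the block). That p lay between 0.000136 and 0.0466 over its alternatives. Without chow 1, 3 or 4 the count was 560, 746 or 2026, and without diet 2, 4 or 5 it was 522, 514 or 502. The call of Taf1a was lost with the block (log2 -1.01), within the slide, without the filter and without chow 1 or 3 or diet 2, 4 or 5 (adjusted p 0.00888 to 0.111), and that of MM9LINCRNAEXON10507-_P1 within the slide (0.000622 to 0.0654).

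After 12 weeks of the diet, adipose tissue had the most changes of the 15 comparisons with a control group. Gusb, the lysosomal beta-glucuronidase, rose 6.67-fold (log2 2.74, SE 0.23, n = 5 per group), Csprs 4.34-fold (log2 2.12, SE 0.32) and Hmgcs1 3.93-fold (log2 1.98, SE 0.24). Rpl13a, a protein of the large ribosomal subunit, rose 2.59-fold (log2 1.38, SE 0.16) and Actb rose 2.34-fold (log2 1.23, SE 0.16). Amy2a5, a pancreatic amylase, fell 3.98-fold (log2 -1.99, SE 0.45). Mia3 fell 3.64-fold (log2 -1.87, SE 0.14), and the chemokine genes Ccl21b (log2 -3.06, SE 1.08), Ccl21c (log2 -2.76, SE 0.94) and Gm13304 (log2 -3.05, SE 1.06) were lower with overlapping groups, all 4 chosen after their values were seen. Some probes for pheromone receptors of the Vmn1r family were lower, while others of the family were not called. Vmn1r186 was at least 2.16-fold lower, and Vmn1r135 4.42-fold, Vmn1r257 4.37-fold and Vmn1r259 4.08-fold, each of these above background on 2 of 5 diet arrays. With normexp the log2 values of Vmn1r186, Vmn1r135, Vmn1r257 and Vmn1r259 were -0.77, -0.83, -0.80 and -0.77, and after quantile normalization those of the last 3 were -1.47, -1.44 and -1.36. Probes named as negative were well above background in 14.1% to 28.6% on the diet arrays and 23.8% to 47.2% on the chow arrays. MM9LINCRNAEXON10939+_P1 rose 14.7-fold (above background on 3 of 5 chow arrays), and humanlincRNA2237-_P1 was at least 2.78-fold lower. Their log2 values were 3.88 and -3.74 as fitted and 2.22 and -0.83 with normexp, and that of Mia3 was -1.12 with normexp. In the deposited log2 table humanlincRNA2237-_P1 was at -2.62, Ccl21b at -3.69, Ccl21c at -3.42 and Gm13304 at -3.70. Of 96 named genes, 33 were higher and 20 lower. Limma called 19910 of 44655 features, 7883 higher and 12027 lower, and 16496 with the slide as a random block, all of them also called without it in the same direction. The diet arrays lay on 1 slide and the chow arrays on others, so the random block cannot separate diet from slide. The higher share was 39.6%, 51.1% after quantile normalization and 22.3% with the percentile over features detected on every array, and the median log2 difference of all features was -0.11, 0.04 and -0.32. With the slide block the log2 values of Ccl21b, Ccl21c and Gm13304 were -3.04, -2.75 and -3.04, close to those without it, but their calls were lost (adjusted p 0.00589 to 0.0812, 0.00578 to 0.0682 and 0.00563 to 0.0742). Without diet 3 the values were -2.12, -1.98 and -2.11, and without diet 2 they were -3.89, -3.45 and -3.86. Each was also lost without chow 1, chow 5, diet 3 or diet 5, Ccl21b and Gm13304 without chow 3, and Ccl21b without chow 4.

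In ob/ob adipose tissue, 3 probes for the CCL21 chemokine, which draws lymphocytes and dendritic cells to lymph nodes, showed the largest fall of all named genes. Ccl21b was 46.4-fold (log2 -5.54, SE 0.93, n = 5 per group), Gm13304 39.5-fold (log2 -5.31, SE 0.93) and Ccl21c 26.5-fold (log2 -4.73, SE 0.78) below wild type. Fam205a2 fell 2.85-fold (log2 -1.51, SE 0.25) and Tfrc 1.98-fold (log2 -0.99, SE 0.24), while Gusb rose 2.09-fold (log2 1.06, SE 0.13). MM9LINCRNAEXON10679-_P1, also higher in ob/ob liver, was at least 22.1-fold higher in the main values. Its log2 difference with the slide block was 4.05, which is below that bound. Its level was -4.06 on wild type 5 against -6.51 to -5.88 on the other wild-type arrays. MM9LINCRNAEXON12085-_P1 rose 17.4-fold (above background on 2 of 5 wild-type arrays). MM9LINCRNAEXON10667-_P1 was at least 3.11-fold lower. These 3 had log2 values of 5.82, 4.12 and -3.46 as fitted and 2.85, 2.25 and -1.24 with normexp. The first was also lower in the deposited log2 table. Of 87 named genes, 15 were higher and 19 lower. The 13605 calls among 41282 features were 5766 higher and 7839 lower, and normexp moved the higher share from 42.4% to 29.0% and the median of all features from 0.03 to -0.11. With the percentile over features detected on every array the higher share was 50.5% and the median 0.10. Of the wild-type arrays only wild type 5 lay on the slide of the 5 ob/ob arrays. The slide block, which rests on that array, left 8008 calls, 4697 of them also called without the block in the same direction, and without wild type 5 there were 21199. With 1 array, a difference of wild type 5 from the other wild-type arrays cannot be divided between slide and sample. Gusb kept its call with the block (log2 0.93), as did Fam205a2 (log2 -1.76), which lost it with all adipose arrays in 1 fit (adjusted p 0.00057 to 0.178). Tfrc did not (log2 -0.72, 0.00523 to 0.246). The CCL21 values became -4.53 (SE 1.63), -4.55 (SE 1.64) and -3.87 (SE 1.37) for Ccl21b, Gm13304 and Ccl21c, and all 3 calls were lost (adjusted p 0.0721 to 0.0761 with the block, the highest of all alternatives, and 8.68e-05 at the lowest). Without ob/ob 3 the values were -6.44, -6.22 and -5.49.

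**Figure D3:**
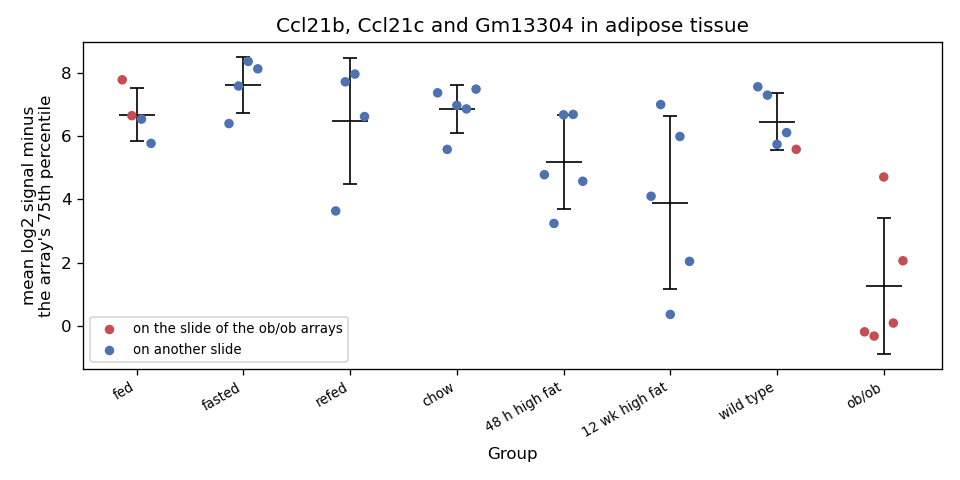
Mean of Ccl21b, Ccl21c and Gm13304 on each adipose array, as log2 signal minus the 75th percentile of the array, by group. Points are arrays, bars the mean and SD, and red points lie on the slide of the ob/ob arrays. The ob/ob arrays lie between -0.32 and 4.71, and the 3 other red points (fed 1, fed 2 and wild type 5) at 5.58 or above.

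Fasting lowered 5 of 84 named genes in muscle and raised none by limma, with 17 at an unadjusted p under 0.05. Tfrc fell 4.97-fold (log2 -2.31, SE 0.35, n = 4 per group) and Disp1 fell 3.05-fold (log2 -1.61, SE 0.28). Tuba1b fell 2.79-fold (log2 -1.48, SE 0.31), Tagap 2.27-fold (log2 -1.18, SE 0.24) and Actb 2.13-fold (log2 -1.09, SE 0.25). MM9LINCRNAEXON10318+_P1 rose 15.8-fold (log2 3.98, SE 0.33), and MM9LINCRNAEXON12123+_P1 fell 5.52-fold (log2 -2.46, SE 0.41, and -1.24 with normexp). Limma called 706 of 38476 features, 281 higher and 425 lower. The slide block gave 645, of which 404 were called in both fits in the same direction, and 542 were called within the slide that held all 4 fed and 2 of the fasted arrays. Between these 2 and the other 2 fasted arrays, on another slide, 1836 features were called. The higher share was 39.8%, 19.8% with normexp and 63.3% with the percentile over features detected on every array, which moved the median of all features from 0.01 to 0.24. Without fed 1 to 4 the count was 248, 286, 207 and 182, and without fasted 2, 3 and 4 it was 397, 470 and 332. Disp1 lost its call without fed 3 or fed 4 (adjusted p 4.32e-05 to 0.0635). The calls of Tuba1b, Tagap and Actb were lost without the filter and without any array but fasted 3, and those of Tagap and Actb also within the slide and after quantile normalization (0.000302 to 0.124, 0.000354 to 0.112 and 0.00109 to 0.139). That of Actb was also lost with the percentile over detected features (log2 -0.86).

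In refed against fasted muscle, limma called 0 of 84 named genes, with 10 at an unadjusted p under 0.05. MM9LINCRNAEXON10318+_P1, which had risen with the fast on the same fasted arrays, fell 9.56-fold (log2 -3.26, SE 0.33, n = 4 per group), and MM9LINCRNAEXON11268+_P1 rose 12.8-fold (log2 3.68, SE 0.52). There were 100 calls among 38476 features, 60 higher and 40 lower. The slide block left 15, and within 1 slide limma called 0 (2102 at an unadjusted p under 0.05). MM9LINCRNAEXON10318+_P1 kept its call with the block (log2 -3.05) and lost it within the slide (adjusted p 2.00e-07 to 0.546 over its alternatives), and MM9LINCRNAEXON11268+_P1 lost it in both and with the replicate block (0.000154 to 0.752). Without fasted 1, 2 or 4 the count was 51, 43 or 228, and without refed 2, 3 or 4 it was 55, 55 or 52. The median of all features moved from 0.03 to -0.07 with the percentile over detected features.

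Muscle showed no called feature after 48 h of high-fat diet: limma called 0 of 37454, with 2851 at an unadjusted p under 0.05, and 0 of 85 named genes, with 8. Hmgcs1 had a log2 difference of 0.02 (SE 0.24, n = 4 per group in muscle) in the model of the 3 tissues. Quantile normalization and the deposited log2 table each gave 1 call, a trended and robust variance gave 2, and 66 features were called without diet replicate 1. All 8 arrays lay on 1 slide.

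In muscle after 12 weeks of the diet, Amy2a5 rose 2.23-fold over chow (log2 1.16, SE 0.20, n = 4 per group). Vmn1r135 rose 6.46-fold (log2 2.69, SE 0.46) and Vmn1r257 rose 4.86-fold (log2 2.28, SE 0.52), each above background on 2 of 4 chow arrays. Probes named as negative were well above background in 25.2% to 34.6% on the diet arrays and 19.7% to 30% on the chow arrays. Vamp7, a protein of vesicle fusion, fell 1.93-fold (log2 -0.95, SE 0.21) and Jrkl fell 3.71-fold (log2 -1.89, SE 0.48). MM9LINCRNAEXON11013+_P1 was at least 4.89-fold and humanlincRNA0744+_P1 at least 4.33-fold higher, and MM9LINCRNAEXON11201-_P1 fell 6.93-fold. With normexp the log2 values of Vmn1r135, Vmn1r257, MM9LINCRNAEXON11013+_P1 and humanlincRNA0744+_P1 were 1.03, 0.89, 1.30 and 1.18, and those of the last 2 were 4.43 and 4.35 as fitted and 3.82 and 3.67 after quantile normalization. Of 85 named genes, 5 were higher and 3 lower. The calls among 37454 features were 6688, 4431 higher and 2257 lower. Chow and 12-week arrays lay on different slides, so diet and slide cannot be told apart in this comparison. The higher share was 66.3%, 49.0% after quantile normalization, 52.9% in the deposited log2 table and 83.5% with the percentile over detected features, which moved the median of all features from -0.01 to 0.16. Jrkl lost its call without chow 1 or 2 and with all muscle arrays in 1 fit (adjusted p 0.00477 to 0.240), and MM9LINCRNAEXON11201-_P1 with all muscle arrays in 1 fit and without diet 4 (0.00632 to 0.117).

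Muscle of ob/ob mice had higher Gusb (1.75-fold, log2 0.81, SE 0.19, n = 4 per group), Tuba1b (1.74-fold, log2 0.80, SE 0.19) and Hprt (1.59-fold, log2 0.67, SE 0.19) than wild type. Nlrp4g, of the NOD-like receptor family, was 1.82-fold (log2 -0.86, SE 0.19) and Gm16513 1.63-fold (log2 -0.70, SE 0.16) lower. In the main values, the probes humanlincRNA1273+_P1 and humanlincRNA0075+_P1 were at least 13.8-fold and 6.92-fold lower, and MM9LINCRNAEXON11880+_P1 was at least 4.62-fold higher. The log2 values of the first 2 were -4.69 and -4.64 as fitted and -1.74 and -1.15 with normexp, and that of the last was 0.99 with normexp. The median signal of the probes named as negative was 11.4 to 44.4 on the wild-type and 5.65 to 9.22 on the ob/ob arrays. Of 92 named genes, 9 were higher and 3 lower. Limma called 8938 of 47033 features, 3771 higher and 5167 lower, with each genotype on a slide of its own, so genotype and slide cannot be told apart. Of the ob/ob calls the higher share was 42.2%, 52.2% after quantile normalization, 52.3% with normexp, 60.4% in the deposited log2 table and 25.7% with the percentile over detected features, and the median of all features moved from 0.02 to -0.12 with the last. Without ob/ob 3 or 4 the count was 4895 or 4051. Gusb lost its call without ob/ob 4 (adjusted p 0.00636 to 0.0515), Tuba1b without ob/ob 3 or 4 and after quantile normalization (0.00672 to 0.101), and Hprt after quantile normalization, with the percentile over detected features and without any array but wild type 4 or ob/ob 1 (0.0114 to 0.224). Nlrp4g and Gm16513 lost theirs with all muscle arrays in 1 fit (0.00640 to 0.298 and 0.00637 to 0.244).

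The 12-week diet was also compared with 48 h of the same diet. In adipose tissue Gusb was 5.24-fold higher (log2 2.39, SE 0.23, n = 5 per group) and Csprs 4.00-fold higher (log2 2.00, SE 0.32), and Vmn1r186 was at least 3.02-fold lower. In liver Ulbp1, a ligand of the killer cell receptor NKG2D, was 2.11-fold higher (log2 1.08, SE 0.19, n = 5 per group) and mouselincRNA0491-_P1 was 6.31-fold lower (log2 -2.66, SE 0.36). In muscle Vmn1r135 was at least 2.92-fold higher, while Tfrc was 2.08-fold lower (log2 -1.06, SE 0.21, n = 4 per group) and Vamp7 1.97-fold lower (log2 -0.98, SE 0.21). With normexp Vmn1r186 in adipose tissue and Vmn1r135 in muscle had log2 values of -0.90 and 0.96, against -3.87 and 2.67 as fitted. Probes named as negative were well above background in 14.1% to 28.6% on the 12-week and 34.1% to 50.5% on the 48 h adipose arrays, and in 25.2% to 34.6% and 8.83% to 24.1% in muscle. Of the named genes, 30 were higher and 13 lower of 96 in adipose tissue, 2 and 1 of 82 in liver, and 11 and 4 of 85 in muscle. Limma called 21685 features in adipose tissue (8733 higher), 3328 in liver (1093 higher) and 7370 in muscle (5555 higher). With the slide as a block 16578 were called in adipose tissue and 2614 in liver, and 1531 within the liver slide that held all 5 of the 12-week and 2 of the 48 h arrays. In adipose tissue and in muscle each group lay on its own slide, so diet and slide cannot be told apart there, with or without the block. Ulbp1 lost its call within that slide (log2 1.12) and with all liver arrays in 1 fit (adjusted p 0.00131 to 0.117). The higher share was 40.3% in adipose tissue, 50.5% after quantile normalization, 56.1% with normexp and 23.7% with the percentile over detected features. In muscle it was 75.4%, 60.2% after quantile normalization, 63.6% in the deposited log2 table and 92.6% with that percentile. The medians of all features were -0.13 in adipose tissue and -0.02 in muscle, and -0.34 and 0.20 with that percentile.

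Whether the 3 tissues responded differently was tested directly. To fasting, 3654 of 20591 features differed between tissues (limma's F-test of the interaction). The largest F among named genes was that of Tfrc, with log2 differences of 1.18 in liver, -0.67 in adipose tissue and -2.31 in muscle (SE 0.34, n = 4 per group). Hmgcs1 differed too, with -1.96 in liver (SE 0.29), -0.03 in adipose tissue (SE 0.27) and -0.44 in muscle (SE 0.27). Refeeding gave 2843 of 19289 features, among them Gusb, with -1.16, -0.14 and 0.45 (SE 0.27), and Zfp131, with -0.58, -0.10 and 0.71 (SE 0.22). After 48 h of high-fat diet 1237 of 30726 features differed. Hmgcs1 was at 1.66 in liver and 1.48 in adipose tissue (SE 0.22) and 0.02 in muscle (SE 0.24), and Taf1a at 0.48, -0.94 (SE 0.19) and 0.14 (SE 0.21). The 12-week diet gave 18692 of 34642, with the largest F among named genes for Gusb, with -0.17 in liver, 2.74 in adipose tissue (SE 0.22) and -0.03 in muscle (SE 0.25), and Vmn1r135, with 0.67, -2.14 (SE 0.34) and 2.69 (SE 0.38). Vmn1r135 is a dim probe. It moved the same way as the range of negative-named probes above background, given above for adipose tissue and muscle. In liver that range was 35.3% to 43.6% on the 12-week and 27.9% to 35.8% on the chow arrays. Whether background accounts for this was not tested. The call of Vmn1r135 was kept over all alternatives (F 25.24 to 69.74). The ob/ob genotype gave 20824 of 39562, with the largest F among named genes for Ccl21c, with 0.12 in liver, -4.73 in adipose tissue (SE 0.55) and 0.79 in muscle (SE 0.61), and with Tfrc at 1.55, -0.99 (SE 0.26) and 0.05 (SE 0.29). No slide term was fitted, so differences between slides enter these tests. The model also uses 1 spread per feature for the 3 tissues, so its SE differ from those of the separate fits given above. They are smaller here for Ccl21c in ob/ob adipose tissue and Hmgcs1 in fasted liver, and larger for Tfrc in fasted liver. In the adipose fit with the slide block the call of Ccl21c was lost. The fasting count was 2369 or 2095 without muscle fed 3 or 4. The refeeding count was 1894, 1627, 1798, 1689, 1704 and 1885 without liver fasted 1, liver fasted 2, liver refed 2, liver refed 3, liver refed 4 and muscle fasted 2. The calls of Gusb and Zfp131 after refeeding were lost with normexp and without the filter, and that of Gusb also after quantile normalization (adjusted p 0.00542 to 0.113 and 0.0123 to 0.135).

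Features called in both the 12-week diet and the ob/ob comparison were counted by direction. These comparisons have no arrays in common. In adipose tissue 2143 were higher in both and 2367 lower in both, where independent lists would give 1064 and 2006, and 2023 went in opposite directions (2923). In muscle 236 were higher in both (405.1 for independent lists), 387 lower in both (170.4) and 454 opposite (541.2). In liver 552 were higher in both (555.5), 285 lower in both (268) and 233 opposite (789.2). Across the features tested in both, the log2 differences correlated at r = 0.135 in adipose tissue, 0.0699 in liver and 0.0082 in muscle, across genes that are not independent replicates. Hmgcs1 was higher in both comparisons in liver, and Gusb was higher and the 3 CCL21 probes lower in both in adipose tissue, with the slide limits given above. The liver count of 837 in the same direction was 555, 382 or 405 without chow 1, 12-week 2 or 12-week 5. The muscle count of 623 was 379, 391, 389 or 363 without chow 1, 12-week 4, ob/ob 3 or ob/ob 4.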

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

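All tests of other splits of the samples, the tests of other normalizations, the test of slide differences as the whole cause of the CCL21 difference, the gap without ob/ob 3 and the condition that left the muscle slide test open were chosen only after the results were seen. The results listed are of these kinds: a value far from the others of its group, a response that differed between tissues, and a signal in spots that no comparison used.

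The first pattern is the 8139 features called in liver between the 12-week diet and chow. Against normalization as the whole cause, 7454 of these were also called in the same direction after quantile normalization and 4459 with normexp, which left 54.8%. The chow and 12-week arrays lay on different slides, and the 48 h arrays lay on both. Of the called features, 67.7% differed between the 2 slides within the 48 h group in the called direction, and the highest share among 10 splits of those arrays was 78.68%. A slide difference may therefore account for part of the calls and cannot be told apart from the diet, since the share lay between the bounds of 60 and 80 set beforehand, and an effect of the long diet stays open as well.

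A second pattern is the 6688 features called in muscle between the 12-week diet and chow. Of these, 5568 were also called in the same direction after quantile normalization and 5908 with normexp, which argues against normalization as the whole cause. Among the called features, the adipose chow arrays differed between slides in the called direction in 34.11%, with 70.1% as the highest share of 10 splits. That met the bound of under 60% set beforehand against slide differences. It cannot exclude them, because the adipose chow arrays cover only 1 of the 2 slides of the muscle comparison, so slide and diet cannot be told apart and an effect of the diet may or may not be involved.

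The third pattern is the lower Ccl21b, Ccl21c and Gm13304 signal in ob/ob adipose tissue. The mean of the 3 genes on wild type 5, the only wild-type array on the ob/ob slide, lay 0.874 log2 above the highest ob/ob array. This is within the gap of 1 that a slide difference was set beforehand to leave, so a contribution of the slide stays open, but it rests on ob/ob 3, without which the gap was 3.52, past the bound of 2 set against the slide. Against the slide as the whole cause, the 3 other adipose arrays on it (fed 1, fed 2 and wild type 5) lay 5.40 log2 above the 5 ob/ob arrays (exact 2-sided permutation p = 0.0357, 56 splits). The real split was not the only extreme one, since another split gave a difference as large in size, with the opposite sign. The largest difference below these was 4.934. Of the 3 arrays, 2 came from another experiment, with mice of 20 weeks against 10 weeks for ob/ob. Lymphoid tissue in the wild-type fat could not be tested, as 0 of 15 markers of T and B cells had a named probe, and it stays open beside an effect of the genotype.

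In most comparisons few other splits gave as many calls as the real one, which makes grouping by chance unlikely without excluding it. These tests were many and were read without correction for their number, and with 35 splits the smallest share possible is 1 of 35. After 48 h in liver, and between tissues for refeeding and for 48 h, another split gave more calls than the real one. Given here are the real count of calls and the highest of the other splits. The splits leave the slide out of account, so they do not exclude it: after 48 h in liver and in adipose fasting few or no calls were left in the slide fits, and in the comparisons with each group on its own slide the real split is also the split by slide. In liver these were 4111 and 80 for fasting, 10447 and 430 for refeeding (1 of 35 splits as large in each), 8139 and 3270 for the 12-week diet, 8974 and 0 for ob/ob, and 3328 and 79 for 12 weeks against 48 h (1 of 100 in each). After 48 h in liver 2 of 100 splits were as large, with 554 and 1092. The split with 1092 calls was the real one with chow 4 and diet 1 exchanged, the same arrays without which the count rose to 1616 and 1754, and the split with 3270 calls for 12 weeks exchanged chow 4 with the first 12-week array. Whether these labels are right was not tested. In adipose tissue the counts were 60 and 0 for fasting (1 of 35), 1338 and 461 for 48 h, 19910 and 2053 for 12 weeks, 13605 and 6985 for ob/ob, and 21685 and 969 for 12 weeks against 48 h (1 of 100 in each). The split with 6985 calls put ob/ob 1 with wild type 1 to 4, which lay on 1 slide. In muscle they were 706 and 1 for fasting, 6688 and 0 for 12 weeks, 8938 and 0 for ob/ob, and 7370 and 1 for 12 weeks against 48 h (1 of 35 in each). Called in the same direction in both the 12-week diet and ob/ob were 837, 4510 and 623 features in liver, adipose tissue and muscle, with 0 as the highest of other splits in each (1 of 100). Since regrouped arrays mostly gave 0 calls to share, this does not test the overlap itself, for which the report gives the counts in each direction beside those of independent lists. In the tests between tissues the counts were 3654 and 380 for fasting, 18692 and 4381 for 12 weeks, 20824 and 1575 for ob/ob (1 of 100), 2843 and 4041 for refeeding and 1237 and 2763 for 48 h (2 of 100).

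For refeeding in adipose tissue and in muscle more of the splits were as large, so grouping by chance stays open there. For adipose refeeding 5 of 35 splits were as large, with 8 calls and up to 5065 in another split, which put fasted 4 with refed 1, 3 and 4 and points to a structure of those samples other than refeeding. For muscle refeeding 3 of 35 were as large, with 100 calls and up to 215, when fasted 4 was put with refed 1 to 3. For 48 h in muscle the real count was 0 calls by limma (2851 features at an unadjusted p under 0.05). All 35 of 35 splits were therefore bound to be as large, with up to 31 calls, and the test decides nothing there.

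Some single arrays lay far from the others of their group, in 20 of 293 groups of values of named genes and lincRNA probes and in 1 of 24 groups of array measures, where chance gives about 1 in 20. In liver these were Gm16513 on chow 4, at log2 -0.87 (others 0.315 to 0.537), Vmn1r186 on chow 4, at -6.31 (-3.75 to -3.16), MM9LINCRNAEXON11950-_P1 on chow 4, at -4.49 (-3.03 to -2.66), and MM9LINCRNAEXON11375-_P1 on fasted 1, at 0.115 (-0.804 to -0.707). Tfrc on fasted 1 was at 7.24 (7.92 to 7.94), MM9LINCRNAEXON11197+_P1 on 48 h diet 2 at -4.83 (-3.97 to -3.72), B020031M17Rik on ob/ob 4 at 2.15 (3.13 to 3.42) and Fam177a2 on wild type 2 at -1.91 (-1.45 to -1.26). Adipose tissue had Mia3 on chow 3 at -1.15 (-1.40 to -1.34), Vmn1r259 on chow 4 at -1.63 (-2.61 to -2.34) and on 12-week diet 4 at -3.11 (-4.80 to -4.47). MM9LINCRNAEXON11005+_P1 on adipose 48 h diet 2 was at -6.81 (-5.07 to -4.45) and MM9LINCRNAEXON10679-_P1 on adipose wild type 5 at -4.06 (-6.51 to -5.88). On the 12-week diet arrays of muscle stood Amy2a5 on replicate 3, at 0.0948 (0.163 to 0.166), MM9LINCRNAEXON11201-_P1 on replicate 4, at -1.93 (-0.936 to -0.91), MM9LINCRNAEXON11294-_P1 on replicate 1, at -1.08 (-0.536 to -0.464), and Nlrp4g on replicate 4, at 1.29 (1.78 to 1.86). H2ac23 on muscle 48 h diet 3 was at -5.60 (-4.50 to -4.42), Vmn1r135 on muscle 48 h diet 1 at -3.69 (-4.67 to -4.57) and Gm16513 on muscle wild type 2 at -0.497 (-0.279 to -0.236). Fasted adipose 4 had 45.5% of features well above background (76.7% to 79.5%).

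A difference between tissues, tested as an interaction, was found for 3654 features in fasting, 2843 in refeeding, 1237 after 48 h of diet, 18692 after 12 weeks and 20824 in ob/ob. In fasting the F values were 26.5 for Tfrc, 22.9 for Hprt, 12.5 for Hmgcs1, 12.2 for Tagap and 11.4 for Disp1. The call of Hprt was lost after quantile normalization (F 0.54, adjusted p 0.000248 to 0.712 over its alternatives). In refeeding F was 11.2 for Hprt, 9.13 for Zfp131 and 9.10 for Gusb. All 3 lost their calls with normexp and without the filter, and Hprt and Gusb also after quantile normalization (0.00125 to 0.388 for Hprt). After 48 h F was 15.5 for Taf1a, 14.9 for Hmgcs1, 9.62 for 4930526I15Rik, 9.16 for Ccdc82 and 8.06 for Gm13304, and the calls of the last 3 were lost without the filter. With the code number shared between tissues as a random block, Gm13304 also lost its call (F 7.70, adjusted p 0.0559, and 0.0115 to 0.100 over its alternatives). Leaving out 1 array also ended them: for 4930526I15Rik liver chow 1 or 3, liver diet 3 or 5 or adipose chow 1 or 3, and for Ccdc82 liver chow 1, 3 or 5, liver diet 2 or 3, adipose chow 2 or 3 or adipose diet 2, 4 or 5. For Gm13304 it was any array of the 28 other than liver chow 4, liver diet 1 or 2, adipose chow 2, adipose diet 3 or 4 or muscle diet 2. After 12 weeks F was 53.5 for Gusb, 47.1 for Vmn1r135, 44.5 for Vmn1r257, 40.7 for Mia3 and 26.3 for Rpl13a. The Vmn1r probes are dim, and the background limit given with the comparisons applies to them. In ob/ob it was 28.8 for Ccl21c, 28.5 for Ccl21b, 26.1 for Gm13304, 23.3 for Tfrc and 21.5 for Taf1a.

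Spots of the probes named as negative, which no comparison used, were well above background in up to 87.8% on 1 array, with 3.25% as the lowest and 31.5% as the median of the arrays. The same flag decided which features entered a fit.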

How the results depend on the processing

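The comparison within 1 slide and the percentile over features detected on every array were chosen only after the data were seen. Over 159 results for named genes and lincRNA probes, 2879 of 3233 alternative values kept the direction and the call, 352 kept the direction and lost the call, and 2 reversed, both for Gm16513 in liver: -0.0917 for refeeding in the deposited log2 table and -0.4624 for 12 weeks of diet with the slide block. The pooled count includes values that could hardly differ from the main fit. The other ways to treat the probes of a gene kept all 159, since no gene among them has several probes. Results that failed the stricter filter are not counted there. In liver fasting the slide block equals the main fit. Leaving out 1 array gave 1434 of the values, in overlapping fits. With the slide block 34 of 109 lost the call and 1 reversed, and within 1 slide 19 of 58 lost it. Counts that moved by more than 1.5 times are given below with the main count in brackets, and the cause was not tested, except that fewer features or arrays enter with the stricter filter, in the deposited table and within 1 slide, and more features without the filter. The filter on signal over background left the fewest features in liver of the feeding experiment. The same flag passed a median of 31.5% of the spots of probes named as negative, so it does not prove detection.

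Normexp gave 4680 for liver 12 weeks (8139), and in adipose tissue 439 for fasting (60), 171 for refeeding (8) and 2634 for 48 h (1338). Between tissues it gave 1784 for refeeding (2843). Quantile normalization gave 123, 40 and 2303 for the same 3 adipose comparisons, 1 for muscle 48 h (0; 2851 at an unadjusted p under 0.05), and 1916 for fasting (3654) and 1561 for refeeding between tissues. Without a filter there were 1508 for liver fasting (4111), 6693 for liver refeeding (10447), 170 for liver 48 h (554), 523 in the liver overlap (837), 771 for adipose 48 h and 325 for muscle fasting (706), and between tissues 1381 for fasting and 668 for refeeding. The stricter filter gave 478, 345 and 12917 for adipose fasting, refeeding and 12 weeks (19910), 3185 for muscle 12 weeks (6688) and 3083 for muscle 12 weeks against 48 h (7370).

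The deposited log2 table gave 5357 for liver 12 weeks and 2196 for liver 12 weeks against 48 h (3328). In adipose tissue it gave 182 for fasting, 122 for refeeding, 2743 for 48 h, 12155 for 12 weeks and 12913 for 12 weeks against 48 h (21685), and in muscle 170 for refeeding (100), 1 for 48 h, 4013 for ob/ob (8938) and 4676 for 12 weeks against 48 h. All arrays of a tissue in 1 fit gave 6292 for liver fasting, 1485 for liver 48 h, 1279 for liver 12 weeks against 48 h, 4248, 4095 and 8178 for adipose fasting, refeeding and ob/ob (13605), and 4990, 2652 and 5387 for muscle fasting, refeeding and ob/ob. A trended and robust variance gave 227 for adipose fasting, 74 for adipose refeeding and 2 for muscle 48 h, and the percentile over detected features 21 for adipose fasting. At an adjusted p under 0.01, 933, 685, 451 and 13768 features differed between tissues in fasting, refeeding, 48 h (1237) and ob/ob (20824).

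The slide block gave 17 for liver 48 h, 434 for liver 12 weeks, 1, 0 (2154 at an unadjusted p under 0.05 in limma), 228 and 8008 for adipose fasting, refeeding, 48 h and ob/ob, and 15 for muscle refeeding. Within 1 slide there were 0 (4389) for liver 48 h, 1531 for liver 12 weeks against 48 h, 0 (1608), 0 (1052) and 248 for adipose fasting, refeeding and 48 h, and 0 (2102) for muscle refeeding. The replicate numbers do not pair the samples, since in every comparison the lowest correlation of same-numbered arrays was -0.00937 or less, and in none did every array correlate best with its own number. The replicate block gave 1118 for liver 48 h, 1 for adipose fasting, 0 for adipose refeeding (8 without it) and 53 for muscle refeeding. Tests of gene lists with an estimated correlation and with fry were not run, as no list had enough named members.

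Leaving out 1 array gave, in liver, 2673 to 3854 for fasting, 67 to 1754 for 48 h, 5080 to 10311 for 12 weeks and 382 to 1099 for the overlap. In adipose tissue it gave 6 to 752 for fasting, 0 to 570 for refeeding, 502 to 2026 for 48 h and 9497 to 21199 for ob/ob. In muscle it gave 182 to 701 for fasting, 43 to 228 for refeeding, 0 to 66 for 48 h, 4051 to 10405 for ob/ob and 363 to 689 for the overlap, and between tissues 2095 to 4787 for fasting and 1627 to 3905 for refeeding. The arrays behind each change of more than 1.5 times are named with the comparisons.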

Other observations

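This part gives values only and reports no test. Counts of called lincRNA probes are given beside those of all features, and no test compared them. After 12 weeks of diet, 339 were higher and 1216 lower of 3416 in adipose tissue, 420 and 383 of 3393 in liver, and 507 and 120 of 2747 in muscle, where all features gave 7883 and 12027, 4370 and 3769, and 4431 and 2257. In ob/ob mice 364 were higher and 555 lower of 2980 in adipose tissue, 155 and 328 of 3793 in liver, and 181 and 456 of 3705 in muscle, against 5766 and 7839, 5794 and 3180, and 3771 and 5167. These directions depend in part on the scaling, as given with the comparisons. After 12 weeks they also went with the share of negative-named probes above background, lower in adipose tissue and higher in muscle. Probes named humanlincRNA had 32 higher and 247 lower in adipose tissue, and 112 and 15 in muscle. In liver that share rose too, with nearly even counts. In ob/ob adipose tissue it was 27.6% to 40.8%, against 10% to 37.6% in wild type, with more lower than higher. Whether background accounts for the counts was not tested. Fasted liver had 143 higher and 36 lower of 1394, and refed liver 367 and 238 of 1394, against 2342 and 1769 and 3541 and 6906.

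Comparisons that share a group have log2 differences that correlate by construction. Fasting and refeeding, which share the fasted arrays, correlated across features at r = -0.205 in liver, -0.703 in adipose tissue and 0.0777 in muscle. Simulated data without any effect gave -0.501, -0.508 and -0.508. When the fasted arrays were divided so that the 2 comparisons shared none, the median r was -0.087, -0.16 and 0.209. The 48 h and 12-week diets, which share the chow arrays, correlated at r = 0.597 in liver, 0.114 in adipose tissue and 0.296 in muscle, against 0.499, 0.507 and 0.502 in simulated data and 0.397, 0.0272 and 0.131 with divided chow arrays.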
